A study of Mus musculus with 13 samples.

How the data were processed

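Total RNA from J774 cells, a mouse macrophage line, was measured on 13 one-colour CodeLink mouse whole genome arrays, with 1 array per sample and no pooling per the labels. The groups were uninfected cells (3 arrays), cells 1 h after infection with Mycobacterium smegmatis (3 arrays), cells 4 h after infection (3 arrays, replicates 1, 3 and 4), and cells given SC-514 before infection and taken at 1 h (2 arrays) or 4 h (2 arrays). SC-514 inhibits the kinase IKK-2, which releases NF-kB from its inhibitor proteins. The 13 samples include neither cells given SC-514 without infection nor cells labelled as given its solvent alone. The labels do not say whether replicates were separate cultures, so every p-value here measures only the spread between these arrays.

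Per the file headers, each array file gives the intensity of a spot as its mean brightness together with the median intensity of the local background. The authors' normalised column and the deposited value table hold the intensity of a spot after subtraction of the local background and division by 1 number per array close to its median, on a linear scale. The deposited table matched the normalised column of every array file to within 1e-06, and array medians in it lay between 0.981 and 0.991. Each array had 35557 spots, with 34937 gene probes, 320 negative control spots and 300 positive control spots. Between 173 and 265 spots per array carried a flag that rejects the spot, and between 14 and 63 were saturated. Between 15727 and 18478 probes per array (45.0% to 52.9%) were flagged as detected. The number of arrays limits the precision.

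Intensities were recomputed from the spot and background columns with limma 3.58.1 in R 4.3.3. Background was corrected by the normexp method with an offset of 50, rejected spots were set to missing, control spots were left out, and arrays were quantile normalised and taken to log2. A probe was kept when it was detected on every array of at least 1 group. Symbols came from the RefSeq accession of each probe: 15663 probes carried one, and 14818 of these matched a gene, giving 13895 symbols on the array. A gene with several kept probes (462 genes) was represented by the probe with the highest mean. This left 17390 features, of which 8698 were named genes and 8692 were probes with no symbol here. Genome positions are not given in the sources used here. The probes of the genes fixed in advance were GE36806 (Tnf), GE34640 (Il1b), GE35801 (Nfkbia), GE33824 (Tnfaip3), GE118349 (Cxcl2), GE36756 (Ccl4), GE35961 (Ptgs2) and GE35815 (Nos2).

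A model of group means over all 13 arrays was fitted with limma (lmFit and eBayes, 8 residual degrees of freedom), and 9 comparisons were taken from it with two-sided moderated tests. P-values were adjusted by the Benjamini-Hochberg method over all features, with a threshold of 0.05. A fold change is given as the log2 difference of group means with its standard error (SE). Where every array of the lower group was below detection, or the higher group was saturated on every array and the lower on none, a fold is a lower bound, computed with each undetected value raised at least to the lowest value of a detected probe on its array, or with the saturated values as measured, and is written as at least that fold.

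The comparisons, the tests, the alternatives and 26 gene lists were chosen before the data were examined, except for the alternatives and the tests of explanations named in the closing section as chosen later, and some simulations. Lists were tested among the named genes with camera (preset correlation of 0.01), with adjustment over the 26 lists of a comparison; camera with an estimated correlation and fry were run beside it. Members past the threshold were counted after adjustment over all features and adjusted over the list alone. Genes named in the text followed a fixed rule. In the first 6 comparisons they were the 6 largest rises and 6 largest falls among genes past the threshold whose groups did not overlap. For each list they were up to 4 members with the smallest p, and in every comparison the 8 genes fixed in advance. Some genes that the rule names are not reported here.

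Numbers in the sample titles were read as slide numbers, which the labels do not state, and on that reading fall into 3 series. Series A held the uninfected arrays, the 1 h infected arrays and replicate 1 of the 4 h infected arrays; series B held the other 4 h infected arrays; series C held the SC-514 arrays. The file headers also place the arrays in 3 date groups. Date group 1 held the uninfected arrays, replicates 1 and 2 at 1 h and replicate 1 at 4 h; date group 2 held the other infected arrays; date group 3 held the SC-514 arrays. Slide series and date group were each used as a block, and comparisons were repeated within each batch that held both groups. A fit with either as a fixed block could not be had for SC-514 against infected or uninfected cells, because no batch holds both.

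Other settings covered the background correction, the scaling of the arrays (array median, median of detected probes, cyclic loess, and the deposited values), the probe filter, the merging of probes, the arrays in the fit, blocks, array weights, the options of eBayes, a threshold of 0.01, a fold of at least 2, and leaving out each array in turn. Where leaving out an array left 1 array in a group, that array was assumed to vary like those of the other groups. The count of induced genes lower with SC-514 was compared with 10 simulated sets without effects and 10 with unrelated effects on the shared arrays. The overlap of the infection calls at 1 h and 4 h was compared with 10 sets of each kind too, and the induced features still higher with SC-514 with 10 sets in which SC-514 changed nothing. Of these simulations, the sets without effects for the induced features lower with SC-514 were planned, and the others were chosen later. The method was tested on simulated data with the means and spreads of these arrays. There, 2-fold changes were recovered for 89.6% of changed genes at 1 h against uninfected cells, 80.6% for SC-514 against infection alone at 4 h and 61.2% for the difference between the effects of SC-514 at 4 h and 1 h. For 1.5-fold changes these shares were 49.3%, 25.4% and 7.46%. The first of these runs made 12 false calls among 17390 features. A shift of 0.5 log2 given to the chemokine list was called in both simulated comparisons, and 0 of the 25 other lists were called by camera. The simulated genes varied independently of each other, while estimated correlations within lists of the real arrays reached 0.184 (cell cycle). That 0 therefore says little about false list calls where genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.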

Results

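Messenger RNA was measured in J774 cells, a mouse macrophage line, before and after infection with Mycobacterium smegmatis, a non-pathogenic relative of the tubercle bacillus. The series asks which genes under the control of NF-kB, the transcription factor that drives inflammatory genes, take part in the killing of such mycobacteria. The 13 arrays fell into 5 groups: uninfected cells (n = 3), infected cells at 1 h (n = 3) and 4 h (n = 3), and infected cells pretreated with SC-514 at 1 h (n = 2) and 4 h (n = 2). SC-514 inhibits IKK-2, the kinase that frees NF-kB from its inhibitors. Between 45.0% and 52.9% of probes were detected per array, and the correlation of log2 intensity between arrays ranged from 0.916 to 0.995. Replicate 4 of the 4 h infected arrays (mean correlation 0.944 with the other arrays) and replicate 3 of the uninfected arrays (0.955) lay farthest from the rest. Changes are log2 fold changes ± SE.

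Within 1 h of infection 9 of 18 chemokines, 8 of 18 cytokines and 5 of 19 immediate early genes rose (3 infected against 3 uninfected arrays). Cxcl2, a chemokine that attracts neutrophils, rose by 6.42 ± 0.09 (85.7-fold, adjusted p = 1.85e-12; its spot was saturated on 1 of the 3 infected arrays). Egr2, a transcription factor of the early response, rose by 3.92 ± 0.11, and Ccrl2, a receptor that binds chemerin, by 3.83 ± 0.14. The chemokines Ccl7 and Ccl3 rose by 3.61 ± 0.25 and 3.34 ± 0.16, and Zfp36, which speeds the decay of cytokine messengers, by 3.24 ± 0.10. The largest falls were smaller. Dusp6, a phosphatase of the kinase ERK, fell (-1.52 ± 0.18, adjusted p = 0.000695), as did Tor4a (-1.31 ± 0.10), Tifab (-1.25 ± 0.14), Trim59 (-1.17 ± 0.20), Zfp61 (-1.13 ± 0.08) and Thap3 (-1.08 ± 0.20).

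Among the genes fixed in advance, the cytokine Il1b rose by 3.20 ± 0.12 (9.21-fold, adjusted p = 3.71e-08), and Tnf by 2.34 ± 0.52 (adjusted p = 0.0334), with Tnf detected on 1 of the 3 uninfected arrays. Nfkbia, the inhibitor of NF-kB that NF-kB itself induces, rose by 1.62 ± 0.07 and the chemokine Ccl4 by 1.38 ± 0.09. Values for Tnfaip3 (0.07 ± 0.12), Ptgs2 (0.42 ± 0.15, undetected in uninfected cells) and Nos2 (-0.08 ± 0.14) did not pass.

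Of the 26 gene lists, 11 were higher at 1 h by camera, and 6 of these calls held with an estimated correlation. Of 18 measured chemokines 9 rose (11 higher and 1 lower adjusted over the list alone; median 0.68, camera adjusted p = 1.3e-18), among them Cxcl3 (2.69 ± 0.13). Of 18 cytokines 8 rose (9 adjusted over the list alone; median 0.41, adjusted p = 1.0e-11), among them the interleukin-1 receptor antagonist Il1rn (2.22 ± 0.13) and Csf2 (1.87 ± 0.15, at least 3.28-fold). Of 19 immediate early genes 5 rose (10 adjusted over the list alone; median 0.44, adjusted p = 4.0e-15), with Ier3 at 3.15 ± 0.12 and Nr4a1 at 3.02 ± 0.27 (at least 6.48-fold). Of 23 NF-kB pathway and feedback genes 6 rose (8 adjusted over the list alone; median 0.34, adjusted p = 5.2e-10), including Traf1 (1.55 ± 0.11) and Nfkbib (0.82 ± 0.12). Of 17 inflammatory effectors and adhesion genes 6 rose (9 adjusted over the list alone; median 0.42, adjusted p = 1.1e-09), including the acute phase gene Saa3 (2.42 ± 0.12) and the adhesion molecule Icam1 (1.38 ± 0.13). Of 24 apoptosis regulators 6 rose (7 adjusted over the list alone; median 0.27, adjusted p = 3.0e-07), including Gadd45a (2.02 ± 0.10) and Cflar (0.69 ± 0.12).

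The other 5 calls were lost with an estimated correlation. Toll-like receptor signalling (4 of 23 higher, with Nod2 at 1.58 ± 0.10 and Tlr2 at 1.15 ± 0.08; camera adjusted p = 0.016) had an adjusted p = 0.0544 with an estimated correlation, and its median of 0.06 turned to -0.03 with the deposited values and to -0.04 within date group 1. The unfolded protein response (2 of 24 higher, Ppp1r15a and Ddit3; camera adjusted p = 0.0030) had an adjusted p = 0.253 with an estimated correlation. The type I interferon response (1 of 20 higher, Irf1 at 1.42 ± 0.11; camera adjusted p = 0.039) and sterol biosynthesis (1 of 20 higher, Dhcr7 at 0.56 ± 0.12; camera adjusted p = 0.042) had adjusted p = 0.365 with an estimated correlation. Macrophage identity (median 0.14 over 15 members; camera adjusted p = 0.025) had an adjusted p = 0.253 with an estimated correlation, and its median was -0.01 with the deposited values. For the granulocyte list the median, mean and test differed in sign.

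In all, 568 of 17390 features passed at 1 h: 260 higher (148 named genes) and 308 lower (134 named genes), with 92 higher and 19 lower by at least 2-fold. The share higher was 45.8%, against 28.8% with arrays scaled by their median, 35.9% with the deposited values and 56.8% scaled by the median of detected probes; the deposited values moved the median of the named genes by -0.11. It was 56.1%, 50.8% and 56.0% without replicate 1, 2 or 3 of the uninfected arrays and 58.5% and 62.2% without replicate 1 or 3 at 1 h, so single arrays turn the balance. The count was 587 (263 higher) with slide series as a block and 455 (237 higher) within series A, and 504 (270 higher) with date group as a block and 254 (178 higher) within date group 1. Cytokine and chemokine medians were 0.41 and 0.68 with slide series as a block and 0.41 and 0.65 with date group as a block. The count fell to 358, 366 and 323 without replicate 1, 2 or 3 of the uninfected arrays, to 311 and 312 without replicate 1 or 3 at 1 h, and to 344 without the 2 arrays farthest from the rest.

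**Figure D1:**
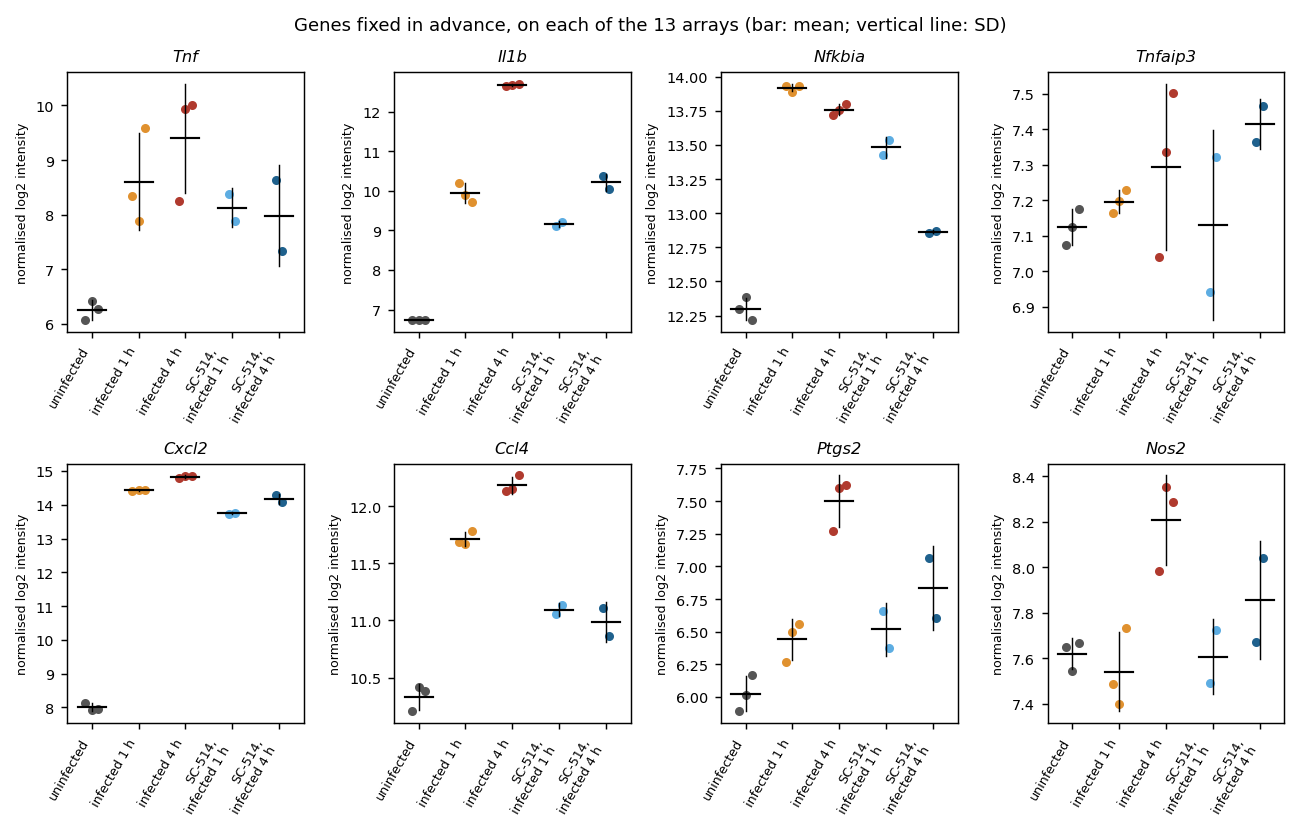
Normalised log2 intensity (vertical axis) of the 8 genes fixed in advance on each of the 13 arrays, by group (horizontal axis), with points for arrays, bars for group means and lines for the SD. Il1b stood 3.20 log2 above uninfected cells at 1 h and 5.93 at 4 h of infection, and 2.43 and 3.47 with SC-514.

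By 4 h of infection 15 of 17 inflammatory effectors, 14 of 18 chemokines and 12 of 18 cytokines had risen (3 infected against 3 uninfected arrays). Il1b rose by 5.93 ± 0.12 (61.1-fold, adjusted p = 1.06e-10), the cytokine Il6 by 5.75 ± 0.21 (at least 44.9-fold), the chemokine Cxcl3 by 5.71 ± 0.13 (52.5-fold), Saa3 by 5.03 ± 0.12 and the growth factor Csf2 by 4.84 ± 0.15 (at least 25.6-fold). Cxcl2 was saturated on all 3 arrays and at least 114-fold higher. Klf2, a transcription factor that restrains macrophage activation, fell (-2.32 ± 0.20, adjusted p = 1.75e-05), as did Klhl6 (-2.24 ± 0.15), the phosphatase Ptpro (-2.16 ± 0.10) and Tifab (-2.11 ± 0.14). Lbh fell too (-2.18 ± 0.13), with a second probe at -0.79.

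Of the genes fixed in advance, Tnf rose by 3.14 ± 0.52 (adjusted p = 0.00165), Ccl4 by 1.85 ± 0.09, Ptgs2, the inducible cyclooxygenase, by 1.48 ± 0.15 (at least 2.28-fold), Nfkbia by 1.46 ± 0.07 and Nos2, the inducible nitric oxide synthase, by 0.59 ± 0.14. Tnfaip3 (0.17 ± 0.12) did not pass. On infected arrays of date group 1 Tnf stood at 8.34 and 7.88 (1 h) and 8.25 (4 h). In date group 2 it stood at 9.59 (1 h) and 9.93 and 10.02 (4 h), so its values followed date group more than time.

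Of 17 inflammatory effectors and adhesion genes 15 rose (15 adjusted over the list alone; median 1.32, camera adjusted p = 4.8e-16), among them the collagenase Mmp13 (2.53 ± 0.14), the lectin receptor Clec4e (3.15 ± 0.23) and Icam1 (1.74 ± 0.13). Of 18 chemokines 14 rose (14 adjusted over the list alone; median 1.61, adjusted p = 4.8e-16), with Ccl3 at 4.14 ± 0.16. Of 18 cytokines 12 rose (14 higher and 1 lower adjusted over the list alone; median 1.53, adjusted p = 4.5e-14), with Il1rn at 4.48 ± 0.13. Of 23 NF-kB genes 12 rose and 1 fell (14 and 1 adjusted over the list alone; median 0.56, adjusted p = 5.2e-07), with Traf1 at 1.84 ± 0.11 and the kinase Ikbke at 1.70 ± 0.19. Of 22 oxidative stress genes 12 rose (14 adjusted over the list alone; median 0.64, adjusted p = 1.2e-06), with the haem-degrading enzyme Hmox1 at 2.87 ± 0.13 and Gclm, which makes glutathione, at 1.80 ± 0.26. Of 23 Toll-like receptor genes 8 rose (8 adjusted over the list alone; median 0.21, adjusted p = 0.00067), with the kinase Ripk2 at 1.80 ± 0.09 and Tlr2 at 1.12 ± 0.08. Of 19 immediate early genes 8 rose and 3 fell (the same counts adjusted over the list alone; median 0.26, adjusted p = 0.0029), with Egr2 at 2.14 ± 0.11. These 7 calls held with an estimated correlation.

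A further 4 calls did not hold with it. Of 20 interferon response genes 8 rose (median 0.43, camera adjusted p = 0.00067), including Socs1 (1.12 ± 0.09), Ifit1 (1.11 ± 0.12) and Irgm1 (1.43 ± 0.21), with an adjusted p = 0.17 with an estimated correlation. Of 30 lysosomal membrane and vacuolar ATPase genes 6 rose and 1 fell (camera adjusted p = 0.012; adjusted p = 0.248 with an estimated correlation), and their median of 0.27 turned to -0.01 with the deposited values. The proton pump subunits Atp6v1h (0.68 ± 0.09) and Atp6v1e1 (0.50 ± 0.10) were among those that rose. Of 24 unfolded protein response genes 6 rose (camera adjusted p = 0.034; adjusted p = 0.472 with an estimated correlation), and their median of 0.13 turned to -0.10 with the deposited values. Of 29 cell cycle genes 1 rose and 6 fell (median -0.18, camera adjusted p = 0.023), including Cdc6 (-1.56 ± 0.09), Tk1 (-0.98 ± 0.10) and Ccnd1 (-0.76 ± 0.10), with an adjusted p = 0.499 with an estimated correlation.

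The other 15 lists were not called at 4 h by camera. Counts of members higher and lower were 9 and 6 of 24 for apoptosis regulators (adjusted p = 0.063; Casp4 at 1.14 ± 0.08), 1 and 5 of 20 for sterol biosynthesis (0.094; Lss at -0.59 ± 0.10) and 3 and 2 of 34 for lysosomal hydrolases (0.45; Gla at 1.53 ± 0.11). They were 4 and 2 of 32 for Rab GTPases (0.49; Rab20 at 2.69 ± 0.13), 2 and 8 of 44 for SNAREs, tethers and sorting complexes (0.87) and 3 and 2 of 20 for phagocyte oxidase and phagocytic receptors (0.45; Marco at 1.38 ± 0.16). Without the 2 arrays farthest from the rest, the SNARE and phagocyte lists each had 1 higher and 1 lower. Hypoxia and glycolysis had 5 of 21 higher (0.13; Hk2 at 1.67 ± 0.20 and Slc2a1 at 1.29 ± 0.16), heat shock and chaperones 1 of 14 higher (0.58), and autophagy 2 of 22 higher and 1 lower (0.66). Cytosolic ribosomal proteins had 1 of 41 higher (0.45; Rps18 at 0.27 and at -0.06 with the deposited values), oxidative phosphorylation 1 of 32 lower (0.58) and macrophage identity 1 of 15 higher and 1 lower (0.77). Of the markers of other cell types, 1 of 8 lymphocyte genes was higher (0.58; Lck at 0.80 ± 0.19), 1 of 5 fibroblast, epithelial and endothelial genes was lower (0.85; Vwf at -0.34 ± 0.10), and the 7 granulocyte, mast cell and erythroid genes did not pass singly (0.58). The median, mean and test differed in sign for the SNARE and heat shock lists.

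At 4 h 3024 features passed: 1138 higher (683 named genes) and 1886 lower (981 named genes), with 287 higher and 197 lower by at least 2-fold. The count was 951 (451 higher and 500 lower) with slide series as a block and 885 (448 and 437) within series A, which held 1 array at 4 h; it was 1612 (724 and 888) with date group as a block and 836 (441 and 395) within date group 1. Cytokine and chemokine medians were 1.45 and 1.63 with slide series as a block and 1.46 and 1.65 with date group as a block. The share higher was 37.6%, against 50.6% within series A, 52.8% within date group 1 and 18.1% with the deposited values, which moved the median of the named genes by -0.22. The count was 1989 without replicate 3 at 4 h and 1734 without the 2 arrays farthest from the rest.

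Features called at 1 h were mostly called at 4 h too. Of the 260 that rose by 1 h, 227 (87.3%) had also risen at 4 h, where independent lists would share 17.0; of the 308 that fell, 192 (62.3%) had also fallen, where independent lists would share 33.4. The latter count was 94, 109 and 97 without replicate 1, 2 or 3 of the uninfected arrays, and 84 and 77 without replicate 1 or 3 at 1 h. Part of the excess may come from the uninfected arrays that both comparisons share: simulated unrelated effects on them gave means of 14.5 and 24.8 and at most 22 and 31 in 10 draws. Simulated arrays without effects shared 0, which says little, since limma calls few features where nothing changes.

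Between 1 h and 4 h of infection (3 arrays against 3) 11 of 18 cytokines rose further and 5 of 19 immediate early genes fell. Il6 rose by a further 5.07 ± 0.21 (33.6-fold, adjusted p = 3.3e-07), Cxcl3 by 3.03 ± 0.13, Csf2 by 2.97 ± 0.15, Il1b by 2.73 ± 0.12, Saa3 by 2.61 ± 0.12 and Il1rn by 2.26 ± 0.13. Klf2 fell (-2.17 ± 0.20, adjusted p = 8.78e-05), as did Ptpro (-1.93 ± 0.10), Egr2 (-1.77 ± 0.11) and Lbh (-1.74 ± 0.13, second probe -0.63). Ldlrad3 fell (-1.91 ± 0.51), with an SD of 1.49 among the 4 h arrays. Ptgs2 rose by 1.06 ± 0.15, Nos2 by 0.67 ± 0.14, Ccl4 by 0.47 ± 0.09 and Cxcl2 by 0.41 ± 0.09; its spot was saturated on all 3 arrays at 4 h and on 1 at 1 h, so this value is no bound. Values for Tnf (0.80 ± 0.52), Nfkbia (-0.16 ± 0.07) and Tnfaip3 (0.10 ± 0.12) did not pass.

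Of 17 inflammatory effectors 12 rose (16 adjusted over the list alone; median 0.82, camera adjusted p = 2.8e-14), with Mmp13 at 1.76 ± 0.14. Of 18 cytokines 11 rose (11 adjusted over the list alone; median 0.81, adjusted p = 1.0e-11), and of 18 chemokines 9 rose (12 adjusted over the list alone; median 0.49, adjusted p = 2.4e-08), with Ccl5, which attracts T cells, at 1.99 ± 0.19. Of 22 oxidative stress genes 7 rose (13 adjusted over the list alone; median 0.44, adjusted p = 2.0e-06), with Hmox1 at 2.14 ± 0.13. Of 19 immediate early genes 5 fell (6 adjusted over the list alone; median -0.28, adjusted p = 0.0045), with Zfp36 at -0.86 ± 0.10. These 5 calls held with an estimated correlation. Of 20 sterol biosynthesis genes 6 fell (7 adjusted over the list alone; median -0.33, camera adjusted p = 0.00059), with Lss at -0.58 ± 0.10 and Hmgcs1, which makes the precursor of sterols, at -0.73 ± 0.14; the adjusted p = 0.214 with an estimated correlation. Of 29 cell cycle genes 6 fell (median -0.14, camera adjusted p = 0.029), with an adjusted p = 0.612 with an estimated correlation and 0.082 by camera within date group 1. Of 20 interferon genes 6 rose and 1 fell (median 0.18, camera adjusted p = 0.041), with an adjusted p = 0.549 with an estimated correlation. The median, mean and test differed in sign for the phagocyte, autophagy, heat shock, unfolded protein, oxidative phosphorylation and granulocyte lists.

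Between the times 1592 features passed, 740 higher (442 named genes) and 852 lower (455 named genes). The count was 425 (255 higher and 170 lower) with slide series as a block, 336 (213 and 123) within series A, 1410 (687 and 723) with date group as a block, 142 (105 and 37) within date group 1 and 0 within date group 2, where limma had 1 array at 1 h and 2098 of 17311 features had an unadjusted p under 0.05. Cytokine medians stayed at 0.93, 0.84, 0.87 and 0.75 with slide series as a block, with date group as a block, within date group 1 and within date group 2; chemokine medians were 0.41, 0.44, 0.42 and 0.41. The share higher was 46.5%, against 60% with slide series as a block, 63.4% within series A and 73.9% within date group 1, and against 27.9% with the deposited values, which moved the median of the named genes by -0.12, and it was 52.2% without replicate 2 at 1 h and 51.1% without replicate 3 at 4 h. The count was 953 without replicate 2 at 1 h, 1048 without replicate 3 at 4 h and 1052 without the 2 arrays farthest from the rest.

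**Figure D2:**
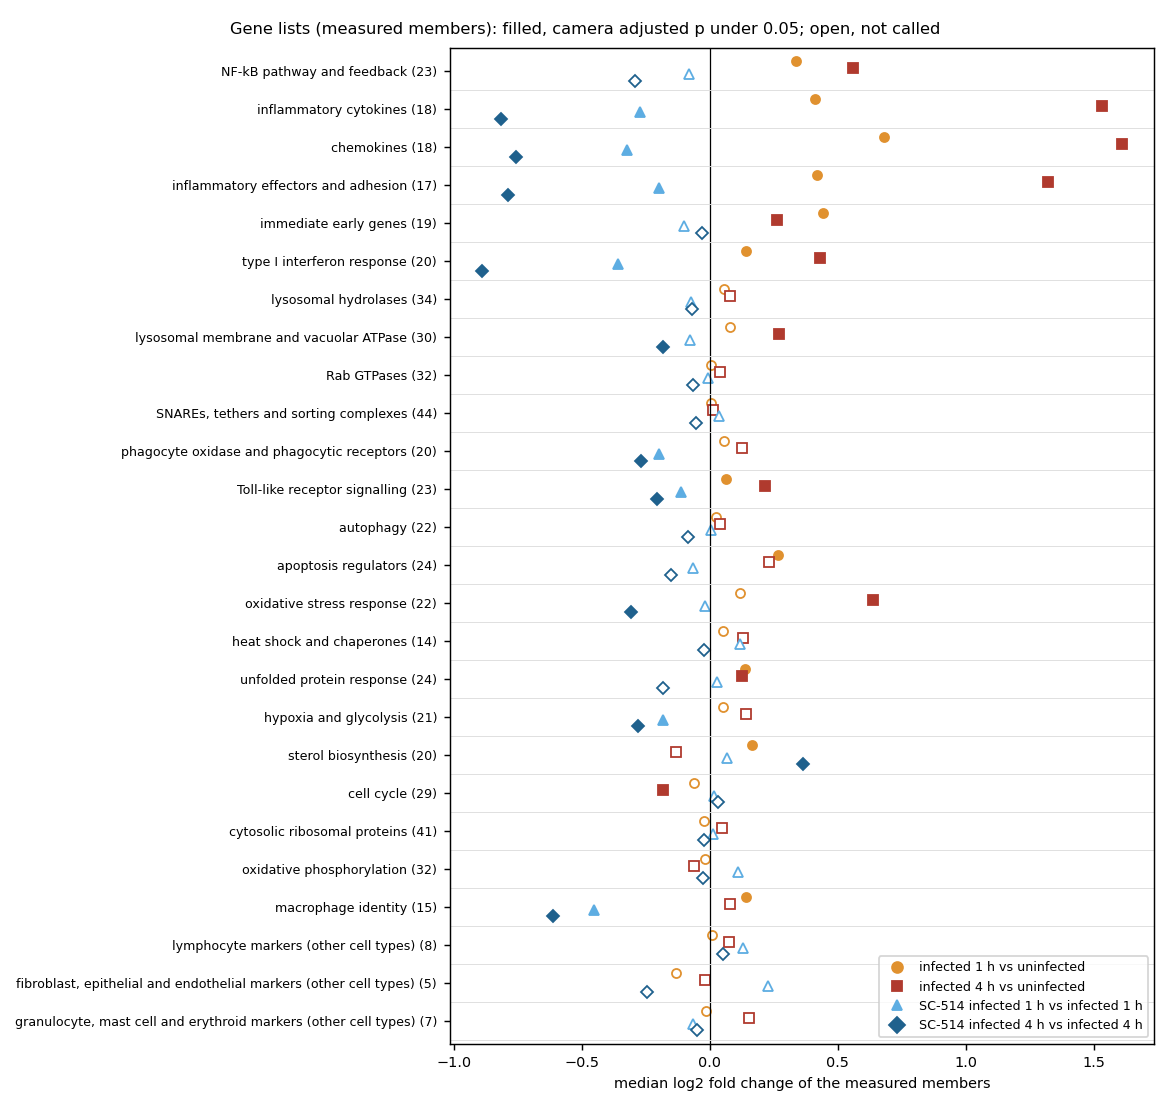
Median log2 fold change (horizontal axis) of the 26 gene lists (vertical axis) for infection against uninfected cells and for SC-514 with infection against infection alone, at 1 h and 4 h; filled points passed by camera. The cytokine median was 0.41 and 1.53 with infection at 1 h and 4 h, and -0.27 and -0.82 with SC-514 against infection alone.

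The arrays of SC-514 treated cells asked what remains of the response when IKK-2 is inhibited. All 4 of these arrays formed slide series C and date group 3, which held no other array, so SC-514, slide series and date group cannot be told apart in any comparison with cells that did not receive it.

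At 1 h (2 arrays with SC-514 against 3 without) genes for chains of C1q, counted under macrophage identity, and 7 of 18 chemokines were lower with SC-514. Chchd10, a mitochondrial protein, was lower (-3.88 ± 0.14, at least 14.6-fold, adjusted p = 5.36e-08), as were the syndecan Sdc3 (-3.01 ± 0.16, 8.08-fold) and Pygl, which breaks down glycogen (-2.88 ± 0.19). C1qa and C1qc, which encode chains of the complement protein C1q, stood at -2.78 ± 0.12 (6.89-fold) and -2.77 ± 0.13, and H2-Aa, a chain of a class II antigen-presenting molecule, at -2.68 ± 0.11 (at least 5.24-fold). Klhl6 was higher by 2.50 ± 0.17 (5.65-fold, adjusted p = 9.80e-06), Lmcd1 by 1.57 ± 0.16, Arl14ep by 1.45 ± 0.13, Clec1b by 1.40 ± 0.12 and Gpt2 by 1.25 ± 0.11. Pxn was higher by 1.97 ± 0.47, with another probe at -0.14. In cells given no SC-514, C1qa differed by 0.29 ± 0.11 between infected and uninfected arrays at 1 h and did not pass.

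Of the genes fixed in advance, Il1b (-0.77 ± 0.13, adjusted p = 0.0078), Cxcl2 (-0.68 ± 0.10, saturated on 1 array without SC-514), Ccl4 (-0.62 ± 0.10) and Nfkbia (-0.44 ± 0.08) were lower. Values for Tnf (-0.47 ± 0.58), Tnfaip3 (-0.07 ± 0.14), Ptgs2 (0.07 ± 0.17) and Nos2 (0.07 ± 0.15) did not pass.

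By camera 8 lists were lower at 1 h, and their medians kept their sign under every scaling of the arrays tried. Of 15 macrophage identity genes 6 were lower (10 adjusted over the list alone; median -0.45, camera adjusted p = 3.4e-09), among them C1qb (-2.61 ± 0.16) and Aif1 (-1.07 ± 0.15); this call held with an estimated correlation. Of 18 chemokines 7 were lower (8 adjusted over the list alone; median -0.32, adjusted p = 9.6e-05; adjusted p = 0.0711 with an estimated correlation), with Ccl12 at -1.57 ± 0.14 and Cxcl3 at -1.53 ± 0.14. Of 20 interferon genes 4 were lower (median -0.36, adjusted p = 0.00027; adjusted p = 0.13 with an estimated correlation), with Irf1 at -1.26 ± 0.12. Of 18 cytokines 4 were lower (5 adjusted over the list alone; median -0.27, adjusted p = 0.0070), with Il1rn at -1.09 ± 0.15 and Il10 at -1.06 ± 0.17. Of 17 effectors 3 were lower (6 adjusted over the list alone; median -0.20, adjusted p = 0.0061), with Icam1 at -0.85 ± 0.14. Of 23 Toll-like receptor genes 3 were lower (4 adjusted over the list alone; median -0.11, adjusted p = 0.0061), with Tlr1 at -1.30 ± 0.13 and Nod2 at -0.96 ± 0.11. These 3 lists had an adjusted p = 0.0645 with an estimated correlation. Of 21 hypoxia and glycolysis genes 5 were lower (median -0.18, adjusted p = 0.0061; adjusted p = 0.179 with an estimated correlation), with Pgam1 at -0.62 ± 0.09. Of 20 phagocyte genes 4 were lower adjusted over the list alone (median -0.20, adjusted p = 0.010; adjusted p = 0.123 with an estimated correlation). The NF-kB list was not called (1 of 23 lower, adjusted p = 0.13). Among markers of other cell types Vwf was lower (-0.63 ± 0.11), as was 1 of 7 granulocyte, mast cell and erythroid genes. Signs differed between median, mean and test for the unfolded protein, sterol and fibroblast lists.

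In all, 828 features differed at 1 h: 257 higher (144 named genes) and 571 lower (346 named genes), with 15 higher and 98 lower by at least 2-fold. The share higher was 31.0%, against 4.94% with arrays scaled by their median and 5.87% with the deposited values, which moved the median of the named genes by -0.18 and -0.33. With slide series or date group as a random block 407 and 531 passed. The count was 525 and 463 without replicate 1 or 2 of the 1 h infected arrays, and 246 and 295 without replicate 1 or 2 of the SC-514 arrays.

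At 4 h (2 arrays with SC-514 against 3 without) several inflammatory genes that infection raised most were lower with SC-514. Il6 was lower (-3.89 ± 0.23, 14.8-fold, adjusted p = 2.13e-06), as was Cxcl3 (-3.03 ± 0.14, 8.17-fold). Chchd10 (-3.69 ± 0.14, at least 12.3-fold), Sdc3 (-3.14 ± 0.16) and H2-Aa (-2.91 ± 0.11, at least 5.63-fold) were also lower. Klhl6 was higher by 3.09 ± 0.17 (8.54-fold, adjusted p = 1.15e-06), the receptor Gpr176 by 2.40 ± 0.14, Xkr5 by 1.61 ± 0.11, the glucocorticoid-induced gene Tsc22d3 by 1.59 ± 0.14 and Cep57l1 by 1.55 ± 0.21. Pxn was higher by 2.38 ± 0.47, with another probe at 0.07.

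Of the genes fixed in advance, Il1b (-2.46 ± 0.13, adjusted p = 1.15e-06), Ccl4 (-1.20 ± 0.10), Nfkbia (-0.89 ± 0.08) and Ptgs2 (-0.67 ± 0.17) were lower, as was Cxcl2, saturated without SC-514 (-0.66 ± 0.10, at least 1.58-fold). Values for Tnf (-1.42 ± 0.58), Nos2 (-0.35 ± 0.15) and Tnfaip3 (0.12 ± 0.14) did not pass. For Tnf the SC-514 arrays (8.63 and 7.33) lay nearer the date group 1 array without SC-514 (8.25) than those of date group 2 (9.93 and 10.02).

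Of 18 cytokines 11 were lower (13 adjusted over the list alone; median -0.82, camera adjusted p = 7.7e-12), with Csf2 at -2.71 ± 0.17 and Edn1 at -2.64 ± 0.15. Of 20 interferon genes 12 were lower (12 adjusted over the list alone; median -0.89, adjusted p = 6.1e-10), with Usp18 at -2.05 ± 0.23, Socs1 at -1.36 ± 0.11 and Ifit3 at -1.20 ± 0.15. Of 17 effectors 10 were lower (14 adjusted over the list alone; median -0.79, adjusted p = 3.9e-08), with Mmp13 at -2.51 ± 0.16, Saa3 at -2.24 ± 0.13 and Cd40 at -1.59 ± 0.18. Of 18 chemokines 9 were lower (11 lower and 1 higher adjusted over the list alone; median -0.76, adjusted p = 1.1e-07), with Ccl12 at -1.99 ± 0.14 and Ccl17 at -1.62 ± 0.13. Of 15 macrophage identity genes 7 were lower (11 adjusted over the list alone; median -0.61, adjusted p = 1.7e-07), with C1qc at -2.81 ± 0.13 and C1qa at -2.72 ± 0.12. Of 23 Toll-like receptor genes 5 were lower (7 adjusted over the list alone; median -0.21, adjusted p = 0.0017), with Tlr1 at -1.45 ± 0.13 and the receptor partner Ly96 at -1.03 ± 0.10. These 6 calls held with an estimated correlation.

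A further 5 calls did not. Of 22 oxidative stress genes 3 were lower (6 adjusted over the list alone; median -0.31, camera adjusted p = 0.0017; adjusted p = 0.145 with an estimated correlation), with Gpx1 at -1.23 ± 0.16 and Hmox1 at -0.95 ± 0.15. Of 21 hypoxia genes 4 were lower (median -0.28, camera adjusted p = 0.013; adjusted p = 0.262 with an estimated correlation), with the glucose transporter Slc2a1 at -1.24 ± 0.18. Of 30 lysosomal membrane genes 5 were lower (median -0.18, camera adjusted p = 0.028; adjusted p = 0.298 with an estimated correlation), with Lamp2 at -0.87 ± 0.20. Of 20 phagocyte genes 3 were lower (median -0.27, camera adjusted p = 0.030; adjusted p = 0.175 with an estimated correlation), with Marco, a receptor for bacteria, at -1.29 ± 0.17 and Fcgr3 at -0.78 ± 0.14. Of 20 sterol genes 3 were higher and 1 lower (camera adjusted p = 0.013; adjusted p = 0.298 with an estimated correlation), and their median of 0.36 turned to -0.11 with arrays scaled by their median. The NF-kB list was not called (1 higher and 4 lower of 23, adjusted p = 0.072). The median, mean and test differed in sign for the immediate early, SNARE and heat shock lists.

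At 4 h 1416 features differed: 534 higher (308 named genes) and 882 lower (548 named genes), with 45 higher and 173 lower by at least 2-fold. The share higher was 37.7%, against 2.65% with arrays scaled by their median, 5.45% with the deposited values and 68.9% scaled by the median of detected probes, which moved the median of the named genes by -0.28, -0.30 and 0.12. The count fell to 241 (37 higher and 204 lower) with only the compared groups in the fit, and to 790 with replicate number as a block. The main fit shares its spread with other groups, such as the SC-514 arrays at 1 h. Residual SDs were 0.0909 on those arrays and 0.181 on the SC-514 arrays at 4 h. With slide series or date group as a random block 857 and 978 passed, and 780 did so without replicate 2 of the SC-514 arrays.

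**Figure D3:**
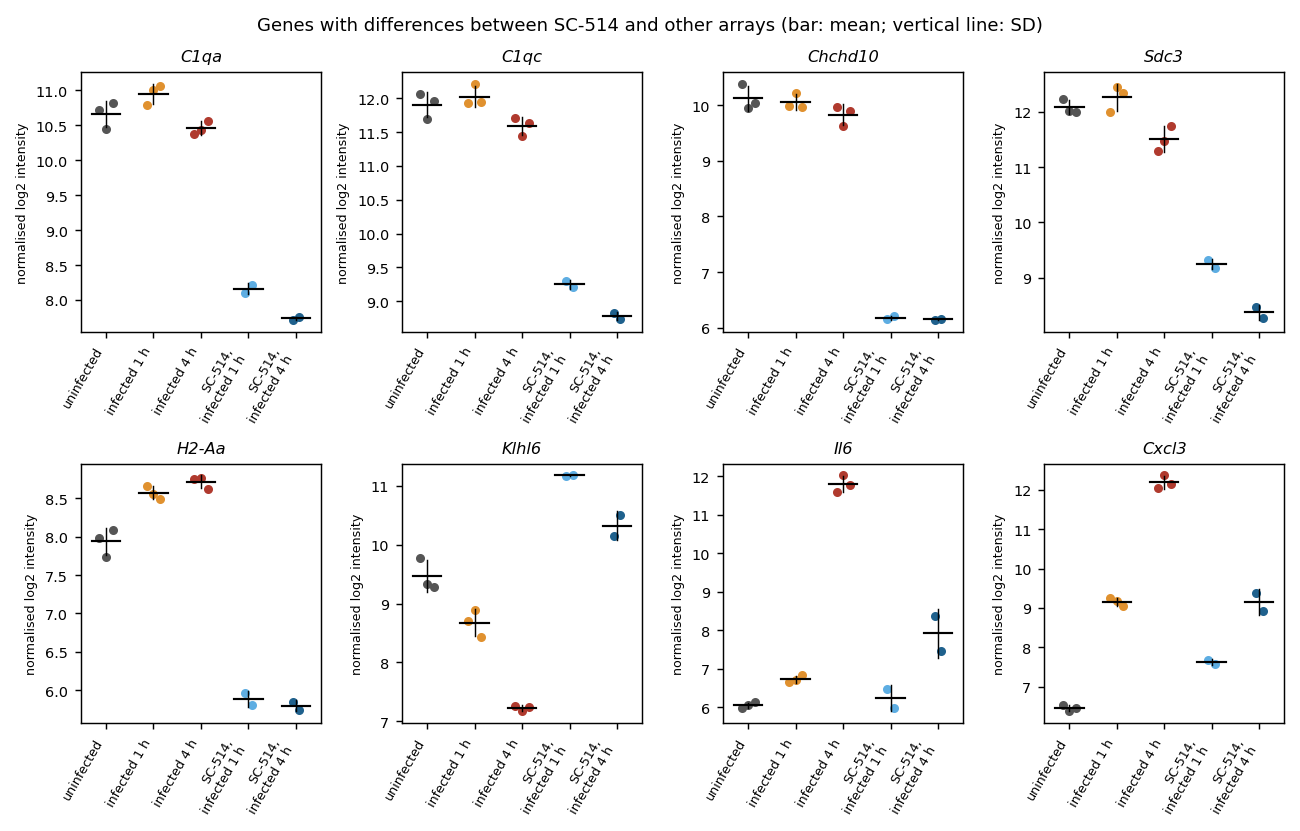
Normalised log2 intensity (vertical axis) of C1qa, C1qc, Chchd10, Sdc3, H2-Aa, Klhl6, Il6 and Cxcl3 on each of the 13 arrays, by group (horizontal axis), with points for arrays, bars for group means and lines for the SD. The SC-514 difference of C1qa was -2.78 log2 at 1 h and -2.72 at 4 h, and that of Il6 was -3.89 at 4 h.

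Some of the genes that infection raised were lower with SC-514. At 1 h 91 of the 260 induced features (35%; 51 named genes) were lower with SC-514, and at 4 h 372 of 1138 (32.7%; 230 named genes). Independent lists would share 8.54 and 57.7. Both comparisons use the infected arrays, so part of the excess may come from these shared arrays. Simulated arrays without effects gave 0 at both times. Simulated unrelated effects gave means of 7.5 and 40.8 and at most 13 and 47 in 10 draws. These simulated sets had shorter lists than the data, which lowers their overlap. They had on average 236.3 and 1013.2 induced features, and 397 and 647.3 lower with SC-514, against 571 and 882 in the data. Over all features the covariance of the infection and SC-514 changes was -0.0131 at 1 h against -0.0151 simulated without effects, and -0.0812 against -0.0149 at 4 h. Among induced features 2 at 1 h and 5 at 4 h were higher with SC-514. Of features that infection lowered, 34 of 308 (11.0%) at 1 h and 279 of 1886 (14.8%) at 4 h were higher with SC-514, against simulated means of 3 and 43. Without replicate 1 or 2 of the 1 h infected arrays the count at 1 h was 59 and 55, and without replicate 1 or 2 of the 1 h SC-514 arrays 39 and 43; without the 2 arrays farthest from the rest the counts were 69 and 272. The count at 1 h was 152 with the deposited values and 175 with array weights, and that at 4 h was 635 with arrays scaled by their median, 121 with only the compared groups in the fit and 241 with replicate number as a block.

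Part of the response was still present with SC-514. Of the induced features 117 of 260 (45%) at 1 h and 421 of 1138 (37.0%) at 4 h were also higher in SC-514 treated infected cells than in uninfected cells. The median rise of the induced features was 0.82 without and 0.43 with SC-514 at 1 h, and 0.63 and 0.33 at 4 h. In simulated arrays where SC-514 changed nothing, 83.6% and 81.5% of induced features were also higher with it, and the medians with it were 0.89 and 0.70. The medians with SC-514 were 0.25 and 0.01 with arrays scaled by their median, where 85 and 173 features were also higher, and 0.33 and -0.01 with the deposited values, where 90 and 209 were; scaled by the median of detected probes 624 were at 4 h. Cxcl2 stood 5.74 ± 0.10 (53.5-fold) above uninfected cells at 1 h and 6.17 ± 0.10 (72.1-fold) at 4 h with SC-514 (2 arrays against 3), and Il1b 2.43 ± 0.13 and 3.47 ± 0.13. The early response gene Egr2 was higher by 3.45 ± 0.13 at 1 h, and the chemokines Ccl7 and Ccl3 were higher by 3.87 ± 0.28 and 3.07 ± 0.18 at 1 h and by 4.45 ± 0.28 and 3.27 ± 0.18 at 4 h. Nfkbia was higher by 1.18 ± 0.08 at 1 h and by 0.56 ± 0.08 at 4 h, and the latter turned to -0.15 with arrays scaled by their median and to -0.19 with the deposited values. Ccl4 was higher by 0.76 ± 0.10 at 1 h and by 0.65 ± 0.10 at 4 h, the latter turning to -0.08 and -0.13. Ptgs2 was higher by 0.81 ± 0.17 (at least 1.44-fold) at 4 h, and the value for Tnf (1.72 ± 0.58) did not pass. Sdc3 and C1qb were below their uninfected levels, with Sdc3 at -2.84 ± 0.16 at 1 h and C1qb at -3.14 ± 0.16 at 4 h.

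Against uninfected cells 6 lists were called at 1 h and 9 at 4 h with SC-514, by camera. Immediate early genes were higher at both times (5 of 19 at 1 h, adjusted p = 2.6e-06; 7 of 19 higher and 1 lower at 4 h, adjusted p = 0.00015), and both calls held with an estimated correlation. Cytokines (4 higher and 1 lower of 18, adjusted p = 0.0058; 6 and 1 at 4 h, adjusted p = 0.00025) had adjusted p = 0.101 and adjusted p = 0.0198 with an estimated correlation. Chemokines (8 higher and 2 lower of 18, adjusted p = 0.00026; 9 and 2 at 4 h, adjusted p = 1.2e-06) had adjusted p = 0.123 and adjusted p = 0.0323 with an estimated correlation, and their medians of 0.16 and 0.63 turned to -0.05 and -0.06 with arrays scaled by their median. Effectors were called at 4 h (8 higher and 1 lower of 17, adjusted p = 2.1e-06), which held with an estimated correlation. NF-kB genes (3 of 23 higher, adjusted p = 0.0015; 8 at 4 h, adjusted p = 0.00015) had adjusted p = 0.198 and adjusted p = 0.113 with an estimated correlation. Apoptosis regulators at 1 h (2 of 24 higher, adjusted p = 0.039; adjusted p = 0.482 with an estimated correlation) turned from a median of 0.16 to -0.05 with arrays scaled by their median. Oxidative stress genes at 4 h (5 of 22 higher and 1 lower, adjusted p = 0.028; adjusted p = 0.331 with an estimated correlation) turned from 0.30 to -0.04. Macrophage identity genes were lower (6 of 15, adjusted p = 0.00014; 6 lower and 1 higher at 4 h, adjusted p = 0.00053), with adjusted p = 0.101 and adjusted p = 0.113 with an estimated correlation. At 4 h interferon genes (5 of 20, adjusted p = 0.0065; adjusted p = 0.331 with an estimated correlation) and cell cycle genes (7 of 29, adjusted p = 0.040; adjusted p = 0.617 with an estimated correlation) were lower. The median, mean and test differed in sign for the lysosomal hydrolase, Rab and granulocyte lists at both times, for the cell cycle, oxidative phosphorylation and fibroblast lists at 1 h, and for the lysosomal membrane, SNARE, Toll-like receptor, autophagy, unfolded protein and ribosomal lists at 4 h.

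In all, 1642 features (465 higher and 1177 lower) at 1 h and 3074 (1092 higher and 1982 lower) at 4 h differed from uninfected cells. The shares higher were 28.3% and 35.5%, against 5.97% and 5.10% with arrays scaled by their median and 59.1% and 72.8% scaled by the median of detected probes. The first scaling moved the median of the named genes by -0.25 and -0.35, the deposited values by -0.44 and -0.55, and the median of detected probes moved it by 0.13 at 4 h. With slide series as a random block 839 and 1701 passed, and with date group 977 and 1916. At 1 h 1016 and 998 passed without uninfected replicate 2 or 3, and 539 and 613 without replicate 1 or 2 of the SC-514 arrays; at 4 h 1921 passed without uninfected replicate 2 and 2013 without replicate 2 of the SC-514 arrays.

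Within the SC-514 treated cells, infection for 4 h rather than 1 h (2 arrays against 2, all in slide series C and date group 3) raised part of the late response. Hmox1 rose by 1.74 ± 0.16 (adjusted p = 0.000717), Gpr176 by 1.71 ± 0.15, Il6 by 1.68 ± 0.25, Cxcl3 by 1.52 ± 0.15, Il1rn by 1.32 ± 0.16 and the lipid carrier Fabp4 by 1.22 ± 0.16. Egr2 fell (-1.64 ± 0.14, adjusted p = 0.000558), as did Klf2 (-1.32 ± 0.25), the pseudokinase Trib1 (-1.28 ± 0.22), Depdc1b (-1.25 ± 0.20), Arid5a (-1.22 ± 0.12) and the apoptosis gene Pmaip1 (-1.17 ± 0.11). Il1b rose by 1.04 ± 0.15 and Nfkbia fell (-0.62 ± 0.09). Values for Cxcl2 (0.43 ± 0.10), Ptgs2 (0.32 ± 0.18), Tnfaip3 (0.28 ± 0.15), Nos2 (0.25 ± 0.17), Ccl4 (-0.11 ± 0.11) and Tnf (-0.15 ± 0.64) did not pass.

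Of 17 effectors 3 rose (7 adjusted over the list alone; median 0.40, camera adjusted p = 5.0e-09), with Cd86 at 0.87 ± 0.15 and the arginine transporter Slc7a2 at 0.82 ± 0.15; this call held with an estimated correlation. Of 18 chemokines 2 rose (6 higher and 1 lower adjusted over the list alone; median 0.23, adjusted p = 0.00020), with an adjusted p = 0.14 with an estimated correlation. Of 18 cytokines 3 rose (adjusted p = 0.013; adjusted p = 0.14 with an estimated correlation), with a median of 0.00 that was -0.07 with arrays scaled by their median and -0.09 with the deposited values. Of 22 oxidative stress genes 1 rose, Hmox1 (adjusted p = 0.0089; adjusted p = 0.284 with an estimated correlation), and the median of 0.17 turned to -0.03 with arrays scaled by their median. Of 29 cell cycle genes 1 fell, Cdc6 (-1.14 ± 0.11; list median -0.18, adjusted p = 0.0029), with an adjusted p = 0.521 with an estimated correlation. Signs differed between median, mean and test for the lysosomal membrane, phagocyte, Toll-like receptor and heat shock lists.

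Between these 2 groups 106 features passed, 70 higher (46 named genes) and 36 lower (26 named genes). Of the 70 higher, 55 were also higher at 4 h than at 1 h without SC-514, and of the 36 lower 31 were also lower, where independent lists would share 2.98 and 1.76. Without replicate 1 or 2 of the 1 h SC-514 arrays the shared counts were 15 and 22 higher, and 7 and 12 lower. The shared lower count was 19, 17 and 18 without replicate 1, 2 or 3 of the 1 h infected arrays, and 20 and 17 without replicate 1 or 3 at 4 h. These comparisons share no array, but both use the same estimate of the spread of each feature, which may add to the overlap. No simulation without effects was run for them. The count was 77 with slide series as a block, 147 with date group as a block, 38 without replicate 1 of the 1 h SC-514 arrays and 249 without replicate 1 of the 4 h SC-514 arrays. With these 4 arrays alone in the limma fit, which is also the fit within series C, 0 features passed and 1168 of 17390 had an unadjusted p under 0.05. The share higher was 66.0%, against 28.6% with arrays scaled by their median and 50% with the deposited values, which moved the median of the named genes by -0.11 and -0.13. It was 47.4% without replicate 1 of the 1 h SC-514 arrays and 30.1% (25 higher and 58 lower) without replicate 2, so 1 array turns the balance.

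The difference of the SC-514 effects at 4 h and 1 h was tested directly over all 4 infected groups. On the log2 scale this difference also takes in any larger change by infection itself at 4 h. The difference was negative for Il6 (-3.39 ± 0.33, adjusted p = 0.00189), Csf2 (-3.16 ± 0.23, adjusted p = 0.000415), Tm4sf1 (-2.01 ± 0.26), the vasoconstrictor Edn1 (-1.87 ± 0.22), Saa3 (-1.86 ± 0.19) and Il1b (-1.69 ± 0.19). It was positive for Gpr176 (1.35 ± 0.21), Xkr5 (1.26 ± 0.15), Ptpro (1.15 ± 0.16), the amino acid transporter Slc43a2 (1.03 ± 0.17) and Zfp652 (0.87 ± 0.14). Differences for Tnf (-0.94 ± 0.82), Ptgs2 (-0.74 ± 0.24), Ccl4 (-0.58 ± 0.15), Nfkbia (-0.46 ± 0.12), Nos2 (-0.42 ± 0.21) and Tnfaip3 (0.19 ± 0.20) did not pass. No difference is given for Cxcl2, which was saturated at 4 h without SC-514.

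Of 18 cytokines 6 had a negative difference (9 adjusted over the list alone; median -0.73, camera adjusted p = 2.3e-14), with Csf3 at -1.66 ± 0.16, and of 17 effectors 2 (6 adjusted over the list alone; median -0.42, adjusted p = 1.8e-06), with Mmp13 at -1.62 ± 0.22; both calls held with an estimated correlation. Of 20 interferon genes 1 was negative (Socs1 at -1.12 ± 0.15; 3 adjusted over the list alone; median -0.40, adjusted p = 1.3e-05), and of 18 chemokines 1 (Cxcl3 at -1.50 ± 0.20; 4 negative and 1 positive adjusted over the list alone; median -0.39, adjusted p = 0.00084). Both had an adjusted p = 0.144 with an estimated correlation. Camera also called 3 lists whose members did not pass singly over all features. Sterol genes had 3 positive adjusted over the list alone (median 0.28, adjusted p = 0.0020; adjusted p = 0.245 with an estimated correlation). Oxidative stress genes had a median of -0.26 (adjusted p = 0.0021; adjusted p = 0.174 with an estimated correlation). Immediate early genes had a median of 0.17 (adjusted p = 0.035; adjusted p = 0.144 with an estimated correlation), which was -0.02 with arrays scaled by their median. The median, mean and test differed in sign for the lysosomal hydrolase, SNARE, phagocyte, heat shock, cell cycle, macrophage identity and lymphocyte lists.

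In all, 42 features had a different SC-514 effect at 4 h than at 1 h: 9 positive (5 named genes) and 33 negative (24 named genes). The count was 13 with slide series as a block and 42 with date group as a block, and cytokine medians were -0.68 and -0.57. Leaving out 1 array gave 18 (uninfected replicate 3), 15, 22 and 16 (replicates 1, 2 and 3 at 1 h), 85 (replicate 1 at 4 h), 20 (replicate 1 of SC-514 at 1 h) and 134 (replicate 1 of SC-514 at 4 h). The share positive was 21.4%, against 10% with arrays scaled by their median and 35% with the deposited values; the first of these moved the median of the named genes by -0.11. It was 52.9% without replicate 1 at 4 h, and 53.7% and 56.8% without replicate 1 or 2 of SC-514 at 4 h, so single arrays turn the balance.

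The SC-514 effects at the 2 times overlapped for 415 features. Of the 257 higher at 1 h, 115 were also higher at 4 h, and of the 571 lower 300 were also lower, where independent lists would share 7.89 and 29.0. The comparisons share no array, but part of the excess may come from the slide series that the SC-514 arrays share. Both also use the same estimate of the spread of each feature, which may add to the overlap. No simulation without effects was run for them. Without replicate 1 or 2 of the 1 h SC-514 arrays, 163 (20 higher and 143 lower) and 169 (31 and 138) overlapped. The shared higher count was also 67, 75 and 59 without replicate 1, 2 or 3 of the 1 h infected arrays, 67 without replicate 3 of the 4 h infected arrays and 73 without replicate 2 of the 4 h SC-514 arrays. Of the 415, 216 were called for infection at neither time. Across the 17390 features the log2 changes at 1 h and 4 h had r = 0.587 and rho = 0.541, and genes are not independent replicates. C1qa, C1qb, C1qc, Chchd10, Sdc3, H2-Aa and Klhl6 were among the 415.

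**Figure D4:**
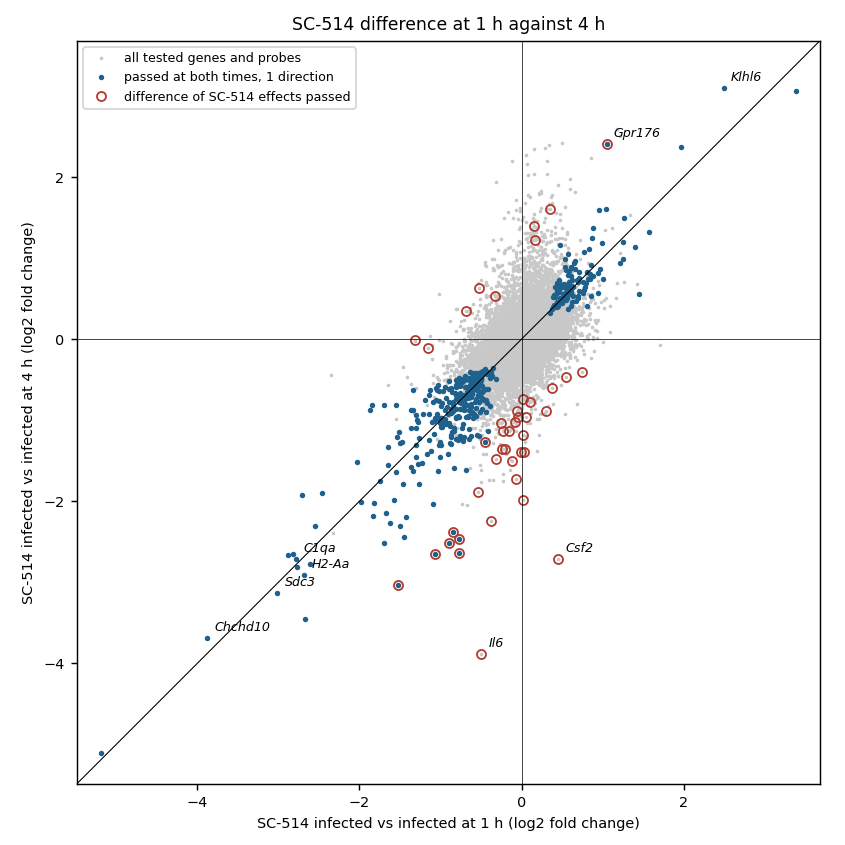
Log2 fold change with SC-514 against infection alone at 4 h (vertical axis) against that at 1 h (horizontal axis) for 17390 features, with the line of equal change. Blue points are the 415 that passed at both times in the same direction, and red circles the 42 whose effects differed between the times.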

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

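The tests of other cell types and of other splits of the arrays were chosen beforehand; the tests of slide series, scaling, single probes, an effect that builds up and array brightness were chosen after the result was seen.

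A test of the difference itself found that the SC-514 effect at 4 h differed from that at 1 h. It was more positive for 9 features and more negative for 33. A larger change by infection at 4 h can give such a difference without any change in the share of it that SC-514 removes. Tm4sf1 had not risen by 1 h of infection (7.101, 6.981 and 7.026, against 6.955, 7.135 and 7.197 in uninfected cells). Uninfected values of Edn1 were 7.103, 7.069 and 7.054. With SC-514 they were 7.034 and 7.139 at 1 h, and 7.313 and 6.948 at 4 h. Il1b, Saa3 and Csf2 had risen by 1 h. The named genes with the largest differences were Il6 (-3.39), Csf2 (-3.16), Tm4sf1 (-2.01), Edn1 (-1.87), Saa3 (-1.86) and Il1b (-1.69) on the negative side, and Gpr176 (1.35), Xkr5 (1.26), Ptpro (1.15), Slc43a2 (1.03) and Zfp652 (0.87) on the positive side. List medians of the difference were -0.73 for cytokines, -0.39 for chemokines, -0.42 for inflammatory effectors, -0.40 for interferon response genes, -0.26 for oxidative stress genes, 0.17 for immediate early genes and 0.28 for sterol biosynthesis. Only the cytokine and effector calls among these 7 lists held with an estimated correlation.

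The first pattern is the 42 features, cytokine genes among them, whose SC-514 effect differed between 4 h and 1 h; 15 to 134 passed with 1 array left out, and without 1 of 3 arrays (replicate 1 at 4 h, replicate 1 or 2 of SC-514 at 4 h) more than 50% were positive (52.9%, 53.7% and 56.8%). Slide series as a fixed block left the median difference of the 42 features at 0.995 of its size (1.17 against 1.18), with 42 in the same direction; 13 passed, 12 of them among the 42, with fewer degrees of freedom left to measure the spread. Dividing each array by its median in place of quantile normalisation left it at 1.02 of its size. With the block, replicate 1 alone stood for infected cells at 4 h, because series B held the other arrays. The 0.995 thus shows only that the difference did not depend on the series B arrays. A shift common to all SC-514 arrays cancels from the difference, so the block cannot bear on series C. The other scaling moved the median of the named genes by only -0.11, which could not shrink a difference of this size much. These values therefore exclude neither as a cause. A smaller rise of cytokine genes under IKK-2 inhibition is a hypothesis that these values leave open, but all SC-514 arrays come from 1 slide series and date group, and a difference between cultures was not tested.

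The second pattern is a set of 415 features, the C1q genes, Chchd10, Sdc3 and H2-Aa among them, that passed in the same direction at both times, with a median shift of 0.75; 163 and 169 passed so without replicate 1 or 2 of SC-514 at 1 h, 216 were called for infection at neither time, and for 8 the effects at the times differed by the test of the difference. Whether the effect grew between 1 h and 4 h stays open: the median growth was 0.0208, but the set had to pass at 1 h, and in only 28.9% of it would 0.5 of the 4 h shift have passed then. Faults of single probes cannot be told apart from a change of the genes: second probes, which exist for 11 genes, moved by 0.502 of the first probes' shift (0.287 to 0.789), 11 of 12 in the same direction. Cells of another type stay open as well: the highest median shift of the 3 marker lists was 0.226 (spread 0.190, fibroblast, epithelial and endothelial genes at 1 h), and the same list stood at -0.24 at 4 h. An effect of SC-514, a different culture, and the slide series and date group that only SC-514 arrays have also stay open, as untested.

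The third pattern is that most probes detected on all arrays were lower on the SC-514 arrays when arrays were scaled by their median. That median was taken over all gene probes, detected or not, and is equal on every array after scaling. The shift is therefore one of detected probes relative to dim ones. At 4 h the positive control spots, for bacterial transcripts added during labelling, shifted by -0.33 as did the 11855 probes detected on all arrays, a ratio of 1.02, which is consistent with array brightness or labelling; single controls ranged from -0.54 to -0.0082, with all 6 below 0. At 1 h the controls shifted by -0.01 against -0.18, a ratio of 0.0428, but single controls ranged from -0.18 to 0.51, so that brightness cannot be told apart from a change in the cells there. No biological explanation was tested.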

How the results depend on the processing

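Most settings were planned. Those chosen after the data were seen are date group (as a block and within groups), scaling by the median of detected probes, and leaving out both arrays farthest from the rest. Setting only spots with the rejecting flag M to missing was also chosen then. Counts are given below where they moved by more than 1.5 times, in the order of the comparisons they name, and the cause was not tested except where stated.

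With an offset of 10, plain subtraction and a filter for detection on all 13 arrays, the count for the difference of SC-514 effects was 27, 18 and 19; the last tests 11541 features. With arrays scaled by their median, counts were 1925 (SC-514 against infected at 1 h), 4569 (at 4 h), 42 (SC-514 4 h against 1 h), 4739 and 6979 (SC-514 against uninfected at 1 h and 4 h), and 635 induced features lower with SC-514 at 4 h. With the deposited values they were 2642, 2644, 32, 5894 and 7483 for the same comparisons, 20 for the difference of effects and 152 induced features lower at 1 h. Cyclic loess gave 68 for SC-514 4 h against 1 h. Scaling by the median of detected probes gave 496, 2517, 36, 2504 and 6734 for those 5 comparisons and 16 for the difference of effects.

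With only the compared groups in the fit, the spread is measured on the arrays of those groups alone. Counts were 1037 (infected 4 h against 1 h), 241 (SC-514 at 4 h) and 13 (difference of effects). For SC-514 4 h against 1 h 0 passed by limma, with 1168 at an unadjusted p under 0.05. Counts were 2749 and 1796 for SC-514 against uninfected cells, and 121 for induced features lower at 4 h. The 2749 lies above the 1642 of the main fit, so having fewer arrays does not account for every move. Residual SDs were 0.0909 on the SC-514 arrays at 1 h and 0.181 on those at 4 h, and the main fit pools them. Replicate number as a block gave 1964 (infected 4 h against uninfected), 932 (infected 4 h against 1 h), 790 (SC-514 at 4 h), 23 (difference of effects) and 241 (induced and lower at 4 h). This block also lost 5 list calls: interferon at 1 h of infection, unfolded protein response at 4 h, hypoxia with SC-514 at 4 h, and apoptosis and cell cycle with SC-514 against uninfected cells. The labels do not say whether the numbers pair the arrays. Residuals of arrays with the same number correlated at 0.13 and 0.32 between 1 h and 4 h of infection, and at 0.32 with SC-514. Between uninfected cells and 1 h of infection they correlated at -0.35, -0.25 and 0.07. Between infected cells at 1 h and SC-514 at 4 h they correlated at 0.46 and 0.56, and between uninfected cells and SC-514 at 4 h at -0.34 and -0.32. Arrays with different numbers reached 0.36 (replicate 2 at 1 h, replicate 1 at 4 h of infection). Residuals in a group of 2 arrays mirror each other, so values for SC-514 groups are not separate. These values do not settle what the numbers mean. Slide series as a fixed block gave 951 and 425 for infected 4 h against uninfected and against 1 h, and 13 for the difference of effects; within 1 series these were 885 and 336, with 0 for SC-514 4 h against 1 h. As a random block it gave 407 and 857 for SC-514 at 1 h and 4 h, and 839 and 1701 against uninfected cells. Date group as a fixed block gave 1612 for infected 4 h against uninfected, and as a random block 531 for SC-514 at 1 h, and 977 and 1916 against uninfected cells. Within date group 1 the infection counts were 254, 836 and 142, and within date group 2 the count for infected 4 h against 1 h was 0 by limma, with 2098 at an unadjusted p under 0.05. With slide series or date group as a fixed block, SC-514 against infected or uninfected cells could not be fitted.

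Array weights gave 938, 6180 and 3556 for infection at 1 h, at 4 h and between them, 2140 and 927 for SC-514 at 1 h and 4 h, 58 for SC-514 4 h against 1 h, 4309 and 1814 against uninfected cells, and 175 induced features lower at 1 h. A stricter threshold of 0.01 left, by construction, 267, 1575 and 735 for infection, 295 and 547 for SC-514, 43 for SC-514 4 h against 1 h, 10 for the difference of effects, 620 and 1271 against uninfected cells, and 44 and 186 induced features lower. A fold of at least 2 left 111, 484 and 211 for infection, 113 and 218 for SC-514, 43 for SC-514 4 h against 1 h, 217 and 374 against uninfected cells, and 17 and 83 induced features lower. Without both arrays farthest from the rest, infection gave 344, 1734 and 1052.

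Leaving out each array in turn gave 311 to 626 and 1989 to 3963 for infection at 1 h and 4 h, 953 to 2065 between them, 246 to 1007 and 780 to 1978 for SC-514 at 1 h and 4 h, and 38 to 249 for SC-514 4 h against 1 h. It gave 15 to 134 for the difference of effects, 539 to 1951 and 1921 to 3488 against uninfected cells, and 39 to 101 and 256 to 405 induced features lower. Features called whichever array was left out numbered 157 higher and 95 lower at 1 h of infection, 624 and 993 at 4 h, 25 and 132 with SC-514 at 1 h, 107 and 351 at 4 h, and 2 and 8 for the difference of effects.

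Of the values of named genes under other settings, 17813 kept direction and side of the threshold, 1244 lost the call, 471 gained one and 22 reversed; with an array left out, 12671 kept both, 723 lost the call and 118 gained one. With arrays scaled by their median, SC-514 against infected at 4 h reversed for Cyld (-0.10), Jun (-0.10), Fdps (-0.052), Sc5d (-0.11) and Tk1 (-0.065). SC-514 at 4 h against uninfected reversed for Nfkbia (-0.15), Ccl4 (-0.084), Cd14 (-0.37), Atg3 (-0.25), Mt1 (-0.006), Fdps (-0.40) and Rps18 (-0.38). With the deposited values, Rps18 at 4 h of infection (-0.059), Icam1 (-0.10) and Mt1 (-0.054) with SC-514 at 1 h against uninfected, and Nfkbia (-0.19), Ccl4 (-0.13), Atg3 (-0.30), Mt1 (-0.043) and Rps18 (-0.42) at 4 h reversed. Scaling by the median of detected probes reversed Acta2 (0.37) and Krt19 (0.39) with SC-514 at 4 h against uninfected. Between 45.0% and 52.9% of probes per array were detected over background, and changes of probes detected on no complete group were not tested.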

Other observations

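The tests of other splits of the arrays were chosen beforehand; the genes of the next paragraph were singled out after their values were seen, and no further test was run on them.

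Some genes of vesicle traffic and lysosomes differed while their lists were not called. Rab20, a small GTPase of endosomes, rose by 2.69 ± 0.13 at 4 h of infection (3 arrays against 3) and was lower with SC-514 at 1 h (-1.36 ± 0.14) and 4 h (-1.57 ± 0.14; 2 arrays against 3). Rab34, which acts at the Golgi apparatus and phagosomes, was lower with SC-514 at 1 h (-0.92 ± 0.14) and 4 h (-1.03 ± 0.14). The lysosomal protease Ctsh was lower at both times (-1.65 ± 0.19 and -1.56 ± 0.19). Gla, a lysosomal galactosidase, rose by 1.53 ± 0.11 at 4 h of infection and was lower with SC-514 at 4 h (-0.64 ± 0.12). The lymphocyte gene Lck rose by 0.80 ± 0.19 at 4 h of infection, in a culture of 1 cell line.

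Other splits of the same 6 arrays were counted for the 3 comparisons of groups of 3. Each has 10 splits, too few for a share under 0.05, and the number of splits with as many features, the real one included, was 1 in each. Every other split mixes arrays of both groups on each side, so a real difference adds to the spread there. Low counts in other splits therefore say little. For infection at 1 h the real split gave 568 and the highest other 0 by limma. For infection at 4 h these were 3024 and 1, and for 4 h against 1 h of infection 1592 and 25. Other splits had at most 1130, 1449 and 3246 features at an unadjusted p under 0.05. The real comparisons had 2340, 5320 and 3923 in the fit of all arrays.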
